A study of Mus musculus with 6 samples.

How the data were processed

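The samples were mouse. Postnatal neural stem cell (pNSC) lines had been grown as neurospheres, floating clusters of cultured neural stem cells, to passages 20 to 24. Mutant lines had been transplanted under the skin of nude mice, which lack a thymus, and 3 of the resulting tumors were collected. They are named here by their sample numbers as tumor 21 (line 3), tumor 4 (line 90) and tumor 5 (line 1), all labelled stage P15-17 and SEGA, the abbreviation of subependymal giant cell astrocytoma. The 3 control pNSC cultures were control 6 (line 26, stage P10), control 7 (line W1) and control 17 (line 86), the latter pair labelled P15-17. The titles of the controls call them wt, the abbreviation of wild type. The labels do not name the mutated gene, the sex of the animals or a batch, and no tumor and control shared a line, so the samples were not paired.

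Per the labels, total RNA was isolated with an RNeasy column kit, and libraries were made with the QuantSeq 3' kit, amplified for 18 PCR cycles and sequenced as single-end reads of 75 nt. Such libraries give about 1 tag per transcript near its 3' end, so counts were not divided by gene length, and a count does not show whether a gene carries a deletion outside the tagged part. The authors named Trimmomatic, STAR 2.5.3a, DESeq2 and the mouse genome build GRCm38 (mm10) in their processing notes. The counting tool, strand setting and annotation were not given in the sources used here. The deposited values were raw read counts per gene symbol, checked to be whole numbers in all 6 columns, for 50508 genes. The kit was used without molecular identifiers as far as the labels state, so PCR copies were counted, and the intervals and floors given here cover counting error only.

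Total counts per library ran from 4867010 to 9449580. A count of 0 in 1 library allows up to 3 counts, which is 0.299 CPM (counts scaled by library size) in control 6 and 0.633 CPM in tumor 4. CPM were computed with effective library sizes from TMM factors, which ranged from 0.834 (control 7) to 1.06 (control 6). Shares of counts were given 95% Wilson binomial intervals. A fold against a group with 0 counts was computed against 3 counts over the whole group and is written as a lower bound. With 1 to 3 counts in the lower group, the ratio is given with its exact 95% binomial interval. Other fold changes are fitted log2 values, tumors minus controls.

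Genes were kept by filterByExpr with its default settings (13074 genes), and the groups were compared with the edgeR 4.0.16 quasi-likelihood test with robust dispersions in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The filter asks for expression in as many libraries as the smaller group holds, so a gene near absent from 1 tumor and from the controls could fail it. Adjusted p-values of single genes are from edgeR. The common biological coefficient of variation was 0.573. An exact permutation of 3 against 3 samples cannot give a p below 0.1. The test was tested on simulated data of this size and spread. Of 100 genes changed 4-fold it recovered 11, and of 100 changed 16-fold it recovered 79, with 9 unchanged genes among 99 calls. DESeq2 1.42.0 recovered 43 and 94 with 90 unchanged genes among 227 calls, and limma-voom recovered 8 and 68 with 7 unchanged among 83.

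Before the data were examined, 40 gene lists were fixed from general knowledge, 19 of cell type markers and 21 of pathways. The 36 lists with at least 3 tested members were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. List p-values are camera's, adjusted over the 36 lists, unless another test is named. Each list was also tested with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. In a simulation with 38 unchanged lists, camera called none of them and found both a raised and a lowered list, the estimated correlation found neither, and fry found the lowered one. Simulated genes varied independently, so this does not show how the preset correlation performs where list members vary together. In the data the estimated correlation ran from -0.278 (Schwann cell list) to 0.897 (mitosis list). The members past the threshold are counted over all tested genes and adjusted over the list alone.

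The genes named in the text were chosen by a rule fixed before the data were examined. It took Tsc1, Tsc2 and Anxa1, among others, whatever their values. It took in each direction the 8 genes with the smallest p among those past the threshold, with a log2 change of at least 1 and no overlap of the groups. It took in each direction the 4 genes with the largest fold change and at least 20 counts in every library of the higher group. It took up to 4 tested members of each list with the smallest p. Predicted gene models, ribosomal genes outside the ribosomal list and bare identifiers were passed over, and clone names were read as bare identifiers after 1 of them had come out under the rule. The text draws on 159 genes from this rule, not all of them described; a few others that it took are not reported here and were not replaced. Any other gene is said to have been chosen after its values were seen. Positions are those of GENCODE vM21 on GRCm38, matched by symbol for 47546 of the 50508 names, and cover the whole gene.

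Alternatives were other tests (DESeq2, limma-voom, a test against a 1.5-fold change), other scalings (median of ratios, upper quartile, none), other filters (none, or a mean count of at least 10), non-robust dispersions, removal of the 50 most abundant genes or of mitochondrial and haemoglobin genes, and leaving out each library in turn. The counts of list members without each library were added after the data were seen. No library was left out of the comparison. Libraries were also compared in pairs for duplicates, and no pair differed by as little as counting error.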

Results

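Gene expression was measured by 3' tag sequencing in 3 subcutaneous tumors grown from mutant mouse pNSC lines and in 3 control pNSC cultures. The comparison asks how the expression profile of the tumors differs from that of control pNSCs. The total counts were 6989131, 4867010 and 6845802 for tumors 21, 4 and 5, and 9449580, 7323496 and 8224305 for controls 6, 7 and 17. Reduced to the shallowest depth, the libraries detected 17350, 24237 and 21236 genes in tumors 21, 4 and 5, against 15044, 16263 and 15229 in controls 6, 7 and 17. Gm42418, a locus overlapping ribosomal RNA, took from 17.6% (95% interval 17.5 to 17.6) of the counts in control 6 to 25.8% (25.8 to 25.8) in control 7. Mitochondrially encoded genes took 1.12%, 1.59% and 1.86% in tumors 21, 4 and 5, and 1.94%, 8.29% and 4.20% in controls 6, 7 and 17. Mutation, growth in a host mouse and any host tissue go together in every sample, so the comparison cannot separate them.

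Marker genes of macrophages, blood, muscle, vessels and connective tissue were among the genes higher in the tumors, and the neural stem cell gene Lfng and the growth factor feedback genes Dusp6 and Spry4 among the lower ones. Of 13074 genes tested, 206 passed the threshold, 147 of them higher and 59 lower in the tumors, and 43 of the 206 belonged to a fixed list. None of the 206 overlapped between the groups, which the choice by small p made likely beforehand. Among all tested genes 27.1% did not overlap, where chance gives 10%. The tumors were not alike: on log2 CPM, tumors 21 and 5 correlated across genes at r = 0.956, while tumor 4 correlated with them at 0.718 and 0.732 and the controls with each other at 0.857 to 0.900 (genes are not independent replicates). The first principal component, 47.6% of the variance, separated tumors from controls, and the second, 25.2%, separated tumor 4 from tumors 21 and 5.

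The count of genes past the threshold depended on single libraries. Without tumor 4 it was 638, and 205 of the 206 were among them. Without control 6 it was 31. By edgeR it was 0 without tumor 21, tumor 5, control 7 or control 17, where 2280, 1853, 3029 and 2340 genes had an unadjusted p under 0.05, DESeq2 called 1578, 1115, 2093 and 1407, and limma-voom called 0, 1, 0 and 0. With all 6 libraries 2493 genes had an unadjusted p under 0.05, DESeq2 called 1770 and limma-voom 73. In each edgeR fit without 1 library the 206 genes kept their sign and an unadjusted p under 0.05. The 206 had been picked for small p in the same libraries, so this was likely beforehand.

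Genes of the pathway named in the title of the series did not pass the test. Tsc1 (ENSMUSG00000026812.16, chromosome 2, 28641228 to 28691167, plus strand) and Tsc2 (ENSMUSG00000002496.10, chromosome 17, 24595816 to 24632630, minus strand) encode the complex that restrains mTORC1. Tsc1 had 14.2 ± 1.62 CPM in the tumors and 21.3 ± 9.91 in the controls (mean ± SD, n = 3 each), a log2 fold change of -0.57 ± 0.42 (SE), and its adjusted p was 0.515 by edgeR. Tsc2 had 12.6 ± 4.35 and 11.8 ± 0.835 CPM, and its adjusted p was 0.924 by edgeR. Anxa1 (ENSMUSG00000024659.15, chromosome 19, 20373428 to 20390944, minus strand), an annexin that binds membrane phospholipids, had 2.20, 9.49 and 4.03 CPM in tumors 21, 4 and 5 and 70.9, 2.13 and 1.86 CPM in controls 6, 7 and 17. Its adjusted p was 0.461 by edgeR, and its log2 fold change of -2.27 ± 1.45 became 1.41 without control 6. A 3' tag count does not show whether a gene carries a deletion elsewhere.

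Macrophage and microglia genes formed the largest group of higher genes from a fixed list. Of 15 tested members 13 rose, or 14 adjusted over the list alone, with a median log2 fold change of 7.61 (7.22 with genes absent from the controls at their bound). Cx3cr1 (ENSMUSG00000052336.7, chromosome 9, 119901616 to 120069879, minus strand), the fractalkine receptor, rose from 0.716 ± 0.280 CPM in the controls to 108 ± 25.2 CPM in the tumors. Aif1, which encodes the microglial protein Iba1, was 741-fold higher (95% interval 132 to 29326, 1 count in the controls), and C1qc, a complement C1q chain, 642-fold (115 to 25409, 1 count). Fcrls, Ms4a6c, Ccl6 and Mpeg1, chosen for their large fold changes, had 0 counts in the controls and were at least 215-fold, 155-fold, 141-fold and 133-fold higher. The list's adjusted p was 3.13e-20 by camera, and its adjusted p = 0.114 with an estimated correlation. The list kept 12 higher members without tumor 4 and 3 without control 6. By edgeR it kept 0 without tumor 21, tumor 5, control 7 or control 17, fits in which no gene passed, with 2280, 1853, 3029 and 2340 genes at an unadjusted p under 0.05.

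Some genes of blood, muscle, vessels and connective tissue were also higher. All 4 tested erythroid genes rose, over all genes and adjusted over the list alone. Hba-a1, an alpha globin whose near-identical copy makes its own count uncertain, was 1176-fold higher (325 to 9721, 2 counts in the controls). Of 11 skeletal muscle genes 5 rose (11 adjusted over the list alone), with Myh4, a fast myosin, 1189-fold higher (213 to 47004, 1 count). Xirp2 and Ttn, also muscle proteins, rose, Ttn by 5.62 ± 0.51 on the log2 scale. Of 11 endothelial genes 4 rose (9 adjusted over the list alone), among them the cadherin Cdh5 and von Willebrand factor Vwf. Of 9 pericyte and smooth muscle genes 2 rose, Rgs5 by 5.32 ± 0.48 and Acta2 by 1.97 ± 0.34, or 7 higher and 1 lower adjusted over the list alone. Of 10 fibroblast genes the collagens Col1a2, Col1a1 and Col3a1 rose (9 adjusted over the list alone). Of 3 adipocyte genes the fatty acid carrier Fabp4 rose (2 adjusted over the list alone). The median log2 fold changes were 9.18, 8.25, 5.72, 4.65, 4.77 and 7.77, and 7.44, 4.91 and 4.65 for muscle, endothelium and fibroblast with genes absent from the controls at their bound.

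For those 6 lists, in the order erythroid, skeletal muscle, endothelium, pericyte, fibroblast and adipocyte, the adjusted p by camera was 3.38e-09, 5.31e-13, 1.07e-09, 5.94e-06, 2.71e-08 and 0.0290. With an estimated correlation none passed: adjusted p = 0.114, 0.210, 0.114, 0.205, 0.248 and 0.347 with an estimated correlation. Without tumor 4 the counts of higher members were 4, 7, 6, 3, 4 and 1, and without control 6 they were 3, 0, 0, 0, 0 and 0. They were 0 by edgeR without tumor 21, tumor 5, control 7 or control 17, where no gene passed and 2280, 1853, 3029 and 2340 had an unadjusted p under 0.05, with 1578, 1115, 2093 and 1407 genes called by DESeq2. Genes of neutrophils, T cells, NK cells and B cells were too low to test, with no gene of these 4 lists above 13.3, 1.62, 2.53 and 5.48 CPM in any library.

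**Figure D1:**
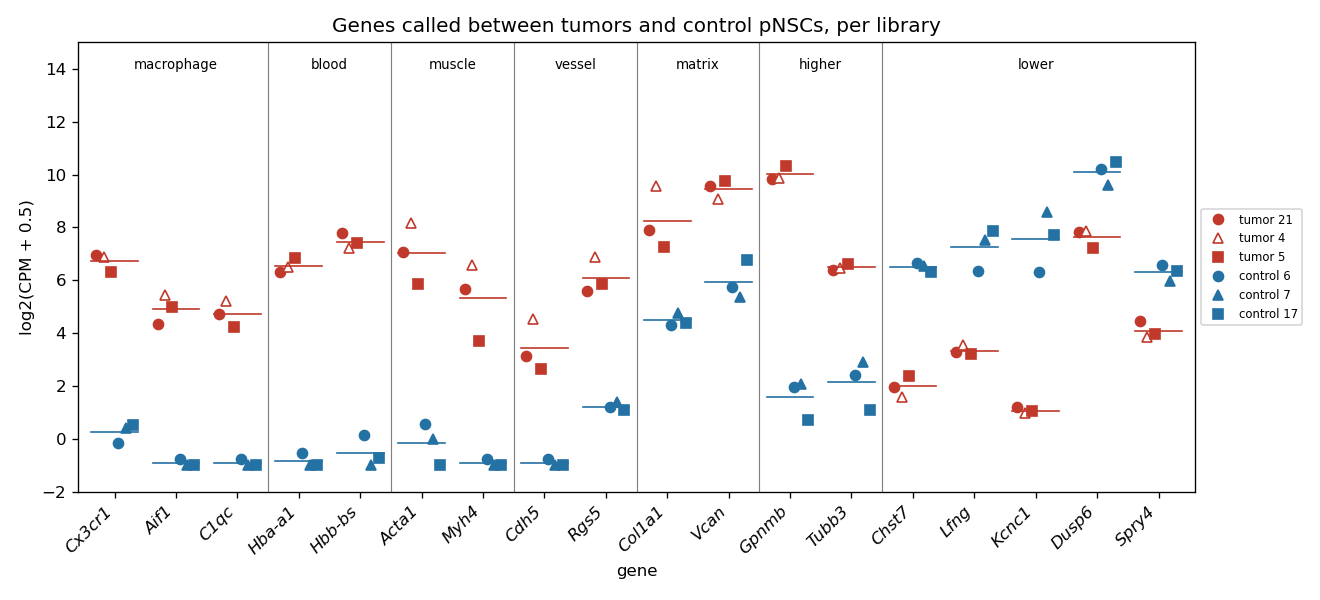
CPM of genes past the threshold on a log2 scale (log2 of CPM + 0.5), each symbol 1 library (tumors red, controls blue, tumor 4 open) and each short line a group mean of the log2 values (n = 3). The tumor and control symbols do not overlap for any gene shown; Gpnmb sits at 1045 ± 203 CPM in the tumors and 2.78 ± 1.41 in the controls, and Chst7 at 3.57 ± 1.12 and 91.2 ± 10.5.

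Of 6 matrix, immune and lysosomal lists with positive medians, 4 had members past the threshold, all of them higher. Of 16 matrix remodelling genes 3 rose (10 adjusted over the list alone): Lox, which crosslinks collagen, by 6.01 ± 0.54 on the log2 scale, the proteoglycan Vcan by 3.40 ± 0.47 and the basement membrane collagen Col4a2 by 4.6 ± 0.70. Bgn, a matrix proteoglycan outside the lists, rose by 8.16 ± 0.69. Of 6 complement genes C4b rose (4 adjusted over the list alone), with 463, 42.2 and 582 CPM in tumors 21, 4 and 5 and 2.09 ± 1.5 in the controls. Of 8 MHC class I genes H2-D1 rose (3 adjusted over the list alone). None of 14 interferon response genes (10 higher adjusted over the list alone) and none of 6 MHC class II genes (5 adjusted over the list alone) passed over all genes. Gpnmb (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929, plus strand), a membrane glycoprotein of lysosomes and melanosomes, rose by 8.56 ± 0.60 and was the 1 lysosomal gene of 18 past the threshold (2 adjusted over the list alone).

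For these 6 lists, in the order matrix, complement, MHC class I, interferon, MHC class II and lysosome, the median log2 fold change was 2.94, 4.97, 1.00, 3.69, 5.92 (5.82 with bounds) and 0.61. The adjusted p by camera was 1.94e-06, 4.94e-05, 0.0334, 1.69e-08, 0.000130 and 0.00200. None passed in the other camera fit: adjusted p = 0.205, 0.205, 0.347, 0.210, 0.279 and 0.482 with an estimated correlation. Without tumor 4 the members past the threshold were 5, 1, 1, 2, 1 and 1, and without control 6 they were 2, 0, 0, 0, 0 and 1. Without tumor 21, tumor 5, control 7 or control 17 they were 0 by edgeR, where 2280, 1853, 3029 and 2340 genes had an unadjusted p under 0.05 and DESeq2 called 1578, 1115, 2093 and 1407.

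**Figure D2:**
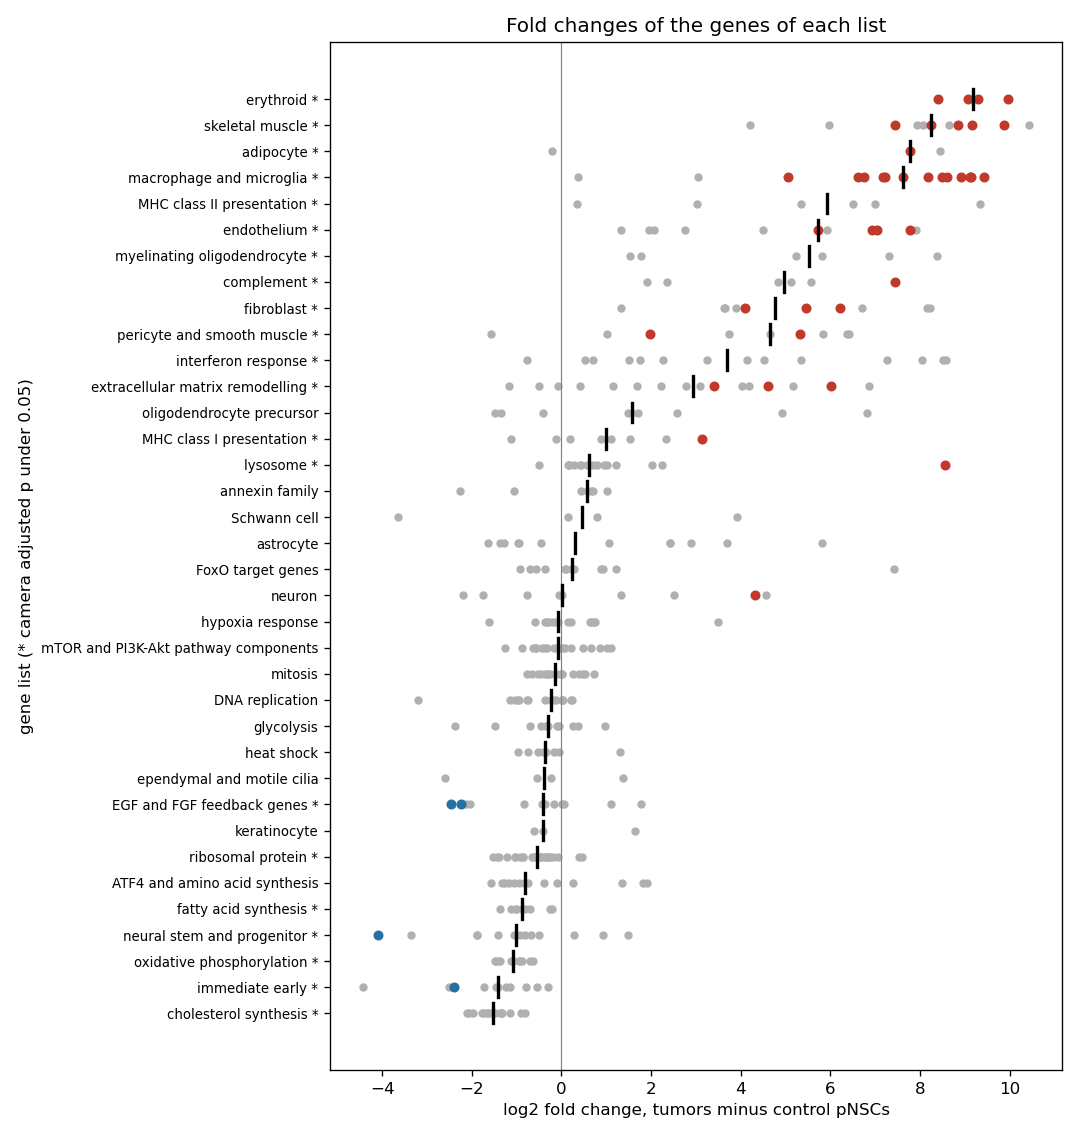
Fitted log2 fold changes (tumors minus control pNSCs) of the tested members of the 36 lists, each dot a gene (red past the threshold and higher, blue past it and lower, grey not past it) and each black bar a list median. Lists with an asterisk had an adjusted p under 0.05 by camera with the preset correlation (14 higher, 7 lower), and 0 lists did with an estimated correlation; the macrophage list has 13 red dots and a median of 7.61.

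Several oligodendrocyte and astrocyte genes split the tumors, not all of them in the same direction. The 6 tested myelinating oligodendrocyte genes had a median log2 fold change of 5.53 and no member past the threshold (4 adjusted over the list alone). Mbp, a major myelin protein, had 388, 2.74 and 452 CPM in tumors 21, 4 and 5 and 0.806 ± 0.916 in the controls. The list's adjusted p was 0.0258 by camera, and the list myelinating oligodendrocyte did not pass with an estimated correlation (adjusted p = 0.521) or by fry (adjusted p = 0.201). The glial filament gene Gfap had 289, 0.211 and 340 CPM in tumors 21, 4 and 5 and 3.85 ± 4.59 in the controls. The oligodendrocyte precursor list (9 tested, 1 higher adjusted over the list alone, adjusted p 0.870 by camera) and the astrocyte list (12 tested, 0 adjusted over the list alone, adjusted p 0.895 by camera) did not pass. The astrocyte genes Gja1 (5.50, 113 and 5.33 CPM in tumors 21, 4 and 5) and Id3 (325, 1473 and 418) and the myelin gene Mal (0.412, 32.3 and 0.288), all chosen after their values were seen, were highest in tumor 4 among the tumors. Gja1 was higher still in control 7, with 153 CPM. Aldh1l1, chosen likewise, had 13.7, 13.5 and 10.4 CPM in tumors 21, 4 and 5. Without tumor 4, 6 myelin genes, 6 precursor genes and 2 astrocyte genes were higher and 1 astrocyte gene was lower. Sox10, a factor of the oligodendrocyte lineage, had 233, 0.211 and 228 CPM in tumors 21, 4 and 5 and 0 counts in the controls, and was not tested because it fell under the filter. Of 9 neuron genes the tubulin Tubb3 rose by 4.32 ± 0.55 (1 adjusted over the list alone), and the list did not pass (adjusted p 0.616 by camera). Tubb3 passed without tumor 4 and in no other fit that left out 1 library.

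**Figure D3:**
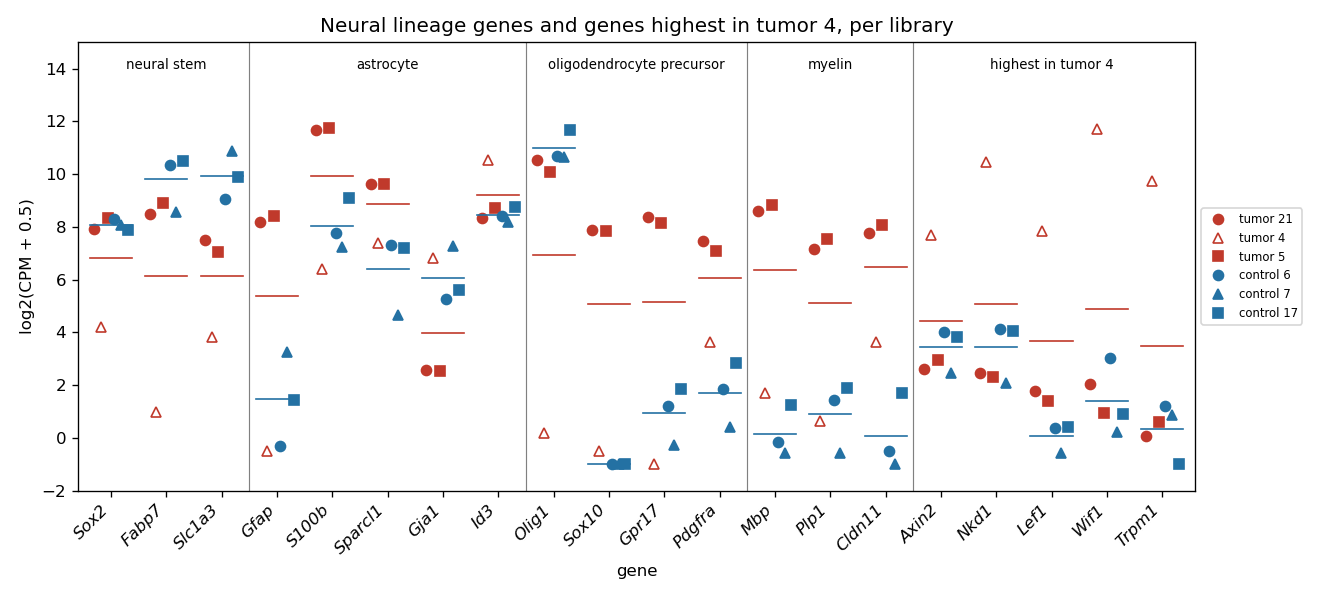
CPM of neural lineage genes and of 5 genes highest in tumor 4 on a log2 scale (log2 of CPM + 0.5), each symbol 1 library (tumors red, controls blue, tumor 4 the open triangle) and each short line a group mean of the log2 values (n = 3); the lineage genes are list members, and all genes shown were chosen after their values were seen. Olig1 had 1490, 0.633 and 1077 CPM in tumors 21, 4 and 5, and Wif1 3.57, 3328 and 1.44.

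Among the lower genes, Chst7 (ENSMUSG00000037347.7, chromosome X, 20059560 to 20097521, plus strand), a sulfotransferase, had 3.57 ± 1.12 CPM in the tumors and 91.2 ± 10.5 in the controls and fell by 4.66 ± 0.35 on the log2 scale. Kcnc1, a voltage-gated potassium channel, also fell, with a log2 fold change of -7.10 ± 0.70, as did the exchange factor Vav3 with -3.26 ± 0.31. The transcription factors Dbx2 and Zic1 (-6.07 ± 0.89 and -3.53 ± 0.41), the adrenergic receptor Adrb1 (-3.5 ± 0.40), Fam181b (-2.68 ± 0.30) and Gcnt4 (-4.64 ± 0.55) were lower as well. St6gal2, a sialyltransferase, had 0 counts in the tumors and was at least 54.7-fold lower, and Golga7b was 146-fold lower (49.7 to 709, 3 counts in the tumors). Lfng (ENSMUSG00000029570.5, chromosome 5, 140607320 to 140615545, plus strand), which modifies Notch, fell by 4.09 ± 0.46 and was the 1 of 15 neural stem and progenitor genes past the threshold (1 adjusted over the list alone). The list was lower, with a median of -1.0 and an adjusted p of 0.000130 by camera (adjusted p = 0.210 with an estimated correlation). Egfr had 2.61, 20.0 and 1.73 CPM in tumors 21, 4 and 5 and 137 ± 84.9 in the controls. Without tumor 4, 3 members of the list were lower. Without control 6, Dbx2 passed (adjusted p 0.0409 by edgeR), while Gcnt4, Adrb1, Fam181b, Zic1, Golga7b and St6gal2 did not (adjusted p 0.0629, 0.0631, 0.0638, 0.0647, 0.111 and 0.125 by edgeR). Chst7, Kcnc1, Lfng and Vav3 passed the threshold without tumor 4 or control 6, and none of them did without tumor 21, tumor 5, control 7 or control 17 (adjusted p from 0.0542 to 0.128 by edgeR).

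The feedback genes of EGF and FGF signalling, the growth factors usual in neurosphere medium, and the immediate early genes had negative medians, with 2 of 12 and 1 of 11 genes past the threshold, all lower. Of 12 feedback genes the MAP kinase phosphatase Dusp6 and the inhibitor Spry4 fell, with log2 fold changes of -2.47 ± 0.35 and -2.24 ± 0.31 (1 higher and 3 lower adjusted over the list alone). Phlda1 had 612 ± 178 CPM in the tumors and 178 ± 37.1 in the controls. The list had a median of -0.41 and an adjusted p of 0.0252 by camera (adjusted p = 0.210 with an estimated correlation). Of 11 immediate early genes Ier2 fell by 2.40 ± 0.38 (3 lower adjusted over the list alone), and Jun had 121 ± 38.3 and 401 ± 46.9 CPM. This list had a median of -1.42 and an adjusted p of 0.000130 by camera (adjusted p = 0.242 with an estimated correlation). Without tumor 4 the lists had 2 and 4 lower members and the feedback list 1 higher. Without tumor 21, tumor 5, control 6, control 7 or control 17 they had 0 by edgeR, with 2280, 1853, 2488, 3029 and 2340 genes at an unadjusted p under 0.05 and 1578, 1115, 1580, 2093 and 1407 called by DESeq2.

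The lists of cholesterol synthesis, oxidative phosphorylation, fatty acid synthesis and ribosomal protein genes were lower by camera, with no single gene past the threshold by edgeR over all genes. None kept the call: adjusted p = 0.301, 0.347, 0.347 and 0.479 with an estimated correlation. All 17 cholesterol synthesis genes had negative fold changes, with a median of -1.52, and 15 were lower adjusted over the list alone. Of the 17 genes, 15 did not overlap between the groups, where chance gives 10% and 27.1% of all tested genes, in either direction, did not overlap. The 13 nuclear oxidative phosphorylation genes had a median of -1.07 (8 lower adjusted over the list alone). Atp5a1, an ATP synthase subunit, had 416 ± 23.6 and 1148 ± 364 CPM. The 9 fatty acid synthesis genes had a median of -0.88 and the 25 ribosomal protein genes of -0.54, each with 0 adjusted over the list alone, and reads shared with ribosomal pseudogenes make the latter uncertain. In this order the adjusted p by camera was 3.38e-09, 2.50e-06, 0.00576 and 0.00148. Mitochondrially encoded genes took 1.12% to 1.86% of the counts in the tumors and 1.94% to 8.29% in the controls.

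Proliferation, stress and pathway component lists did not pass camera with all 6 libraries. The adjusted p was 0.525 for mitosis, where Cdk1 had 250.0 ± 137 CPM in the tumors and 362 ± 139 in the controls, and 0.134 for DNA replication. It was 0.780 for mTOR and PI3K-Akt components, 0.616 for FoxO targets, 0.0725 for ATF4 and amino acid synthesis genes, 0.525 for glycolysis, 0.196 for heat shock and 0.525 for annexins. Rictor, the mTORC2 scaffold, had 36.0 ± 6.03 and 17.8 ± 2.17 CPM, with an adjusted p of 0.119 by edgeR. The list hypoxia response had a median of -0.08 but a test direction of higher (adjusted p 0.396 by camera, and 0.824 by camera with an estimated correlation of 0.801). Without control 6 it passed as higher by camera with the preset correlation (median 1.56, adjusted p 0.000798). By the same test its adjusted p was 0.202 to 0.988 without any other single library. The estimated correlation was not run with a library left out. Ependymal, keratinocyte and Schwann cell lists had an adjusted p of 0.517, 0.727 and 0.622. Adjusted over the list alone, 1 FoxO target and 1 Schwann cell gene were higher, 1 ependymal and 1 Schwann cell gene were lower, and no member of the other lists in this paragraph passed.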

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

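The counts of list members without each library were tests chosen only after the data were seen; the other alternatives were planned. The 206 genes (147 higher, 59 lower) became 1770 (1412, 358) with DESeq2, 73 (50, 23) with limma-voom, 720 (526, 194) without a filter, 85 (61, 24) with a mean count of at least 10 and 110 (82, 28) against a 1.5-fold change. Leaving out 1 library gave 0 to 638 genes (0 to 459 higher, 0 to 179 lower). Median of ratios, upper quartile, no scaling, non-robust dispersions, removal of the 50 most abundant genes and removal of mitochondrial and haemoglobin genes gave 190 to 247. The cause was not tested. The median log2 fold change of all genes moved from 0.01 to 0.84 without a filter and 0.88 with DESeq2, which include more genes, and to 0.15, 0.10 and 0.12 without controls 6, 7 and 17. Fold changes under those settings are read against these shifts.

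The 14 higher lists became 0 and the 7 lower lists 0 with an estimated correlation. The higher lists became 7 when the background left out the genes of non-neural cell types, which removes those lists by construction, and with fry the higher lists became 11 and the lower lists 4. Those lost among the higher were list myelinating oligodendrocyte, list adipocyte and list lysosome (adjusted p 0.201, 0.0511 and 0.0695 by fry). Of 36 lists 2 kept direction and side of the threshold throughout, and 11 reversed somewhere, none of which had passed. Some lists that had not passed did so by camera, in the same direction, with 1 library left out. They numbered 2, 1 and 1 without tumors 21, 4 and 5, and 1, 2 and 1 without controls 6, 7 and 17. Without a filter the test direction reversed for astrocyte, neuron, keratinocyte and FoxO genes (medians 1.05, 0.18, 1.97 and 0.18), and with fry for mTOR components (-0.088). With 1 library left out, the medians of lists that reversed in some fit ran from 0.088 to 1.48 (astrocyte), 1.17 to 2.38 (oligodendrocyte precursor), -0.43 to 0.20 (ependymal), -0.18 to 6.94 (keratinocyte), -0.54 to 0.29 (mitosis), -0.14 to 0.40 (list FoxO target genes), -0.53 to 0.26 (glycolysis), -0.58 to 1.56 (hypoxia) and 0.29 to 1.01 (annexin).

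Of 159 named genes 44 kept sign and side of the threshold throughout and 11 reversed somewhere, none of which had passed. With limma-voom Lipe was 0.64 and Cdh19 -0.0071. With 1 library left out the log2 fold change ran from -0.27 to 0.29 (Tsc2), -3.01 to 1.41 (Anxa1), -1.25 to 0.0019 (Rsph1), -0.47 to 0.089 (Cfap126), -1.88 to 1.13 (Lor), -0.72 to 1.09 (Lipe), -0.26 to 0.71 (Cdh19), -0.85 to 0.09 (Aurka), -4.50 to 0.10 (Pgk1), -1.14 to 0.47 (Ldha) and -2.18 to 0.30 (Pdk1). The cause was not tested. Depth limits genes near 3 counts per group, and the simulated 4-fold changes found, 11 of 100, show that most changes of that size would be missed.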

Other observations

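Among the tests below, those of host tissue, cells of both sexes, Gpnmb, dilution, the swap and shallow sequencing were chosen only after the result was seen; those of melanocyte genes, Wnt targets and other splits of the samples were not. Tumor 4 (line 90) carried a set of transcripts at levels far above those in the other 5 libraries. The genes in this paragraph were chosen after their values were seen. The Wnt inhibitor Wif1 had 3328 CPM in tumor 4 and at most 7.67 CPM elsewhere, Nkd1, a Wnt feedback gene, 1402 against at most 17.0, and the Wnt effector Lef1 230.1 against at most 2.89. Glutamine synthetase Glul had 6248 CPM against at most 168.5, and Trpm1, a channel of melanocytes and retinal bipolar cells, 849 against at most 1.79. Tumors 21 and 5 had 929 and 957 CPM of the glial matrix gene Tnr, against 2.95 in tumor 4.

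The markers of blood, vessel, muscle, fibroblast and macrophage cells in the tumors may come from host tissue inside the dissected tumors. Of the variance of the ratio of tumor 4 to tumor 5 over 70 genes, 48.5% lay between the 9 non-neural lists. The median in 10000 shuffles was 10.9% (permutation p = 1e-04, the smallest these can give). Tissues entering in different shares would give such a result. The shuffles treated genes of a single pair of tumors as replicates, and genes of a list can also vary together within transplanted cells. The test therefore cannot tell host tissue from expression by those cells. Whether cells of both sexes mark the tumors alone stays open: Xist and each of 4 Y-linked genes passed 5 CPM, a threshold set after the values were seen, in 3 of 3 tumors and 0 controls, but control 7 had 437 CPM of Xist with 31.2 CPM of the Y-linked genes together, and counts as 1 control with both by their sum. Expression of some of these genes by the transplanted cells stays open, since no culture of the mutant lines was analysed here.

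Gpnmb and Dct, a melanosomal enzyme chosen after its values were seen (55.9 ± 5.78 CPM in the tumors, 0.231 ± 0.248 in the controls, adjusted p 0.0142 by edgeR), were at similar levels in all 3 tumors. Host macrophages may be the source of Gpnmb. Its ratio between tumors lay 0.85, -1.42 and -2.27 SD from the mean of the macrophage list in the pairs 21 and 4, 21 and 5, and 4 and 5. The first bound, 2 SD in at least 1 pair, would have argued against this source. After that result the bound was changed to all 3 pairs, which are not independent of each other. A bound moved in this way decides nothing, so the source of Gpnmb cannot be told apart here. For Dct, the melanocyte genes Tyr, Tyrp1, Pmel and Mlana together reached 9.60%, 17.7% and 9.25% of its level in tumors 21, 4 and 5, on both sides of the 10% set beforehand, so host melanocytes cannot be told apart from expression by the tumor cells.

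Tumor 4 had little RNA of many neural stem and glial genes: of 46 members of 4 such lists at 10 CPM or more in any tumor, 33 had a log2 ratio below -1 to the lower of the other tumors, 6 had a ratio above 1 to the higher and 7 had neither (median to the lower -4.01, quartiles -6.10 and -0.26). An even dilution by host tissue would raise the 9 non-neural lists alike. Of the variance of the ratios to tumors 21 and 5, 33.9% and 48.5% lay between them (permutation p = 0.0025 and 1e-04). The 48.5% is the value given above for host tissue. Against each tumor 6 of the 9 lists had a positive mean log2 ratio. Controls expressed some of these genes, such as the Schwann cell gene Cdh19 (15.9 ± 11.3 CPM), which had 25.6, 0.844 and 26.4 CPM in tumors 21, 4 and 5. The share can thus hold the loss of neural RNA itself, so this test cannot decide on an even dilution. Such a dilution would also lower all genes made only by the tumor cells by 1 factor. The quartiles of -6.10 and -0.26 over the 46 genes argue against it alone, unless host cells made those that fell little. Whether host cells made them was not measured. A different mix of host tissue also stays open. A test by sex and a pair of lists picked after their values were seen came before this test and were dropped. A swap with a control is argued against by the 15 macrophage genes fixed beforehand, whose median log2 ratio to the lower of tumors 21 and 5 was at most -4.18 in a control and 1.12 in tumor 4, and shallow sequencing by a median of -4.21 (quartiles -6.63 and -0.32) over the same 46 genes with the other tumors thinned to its total count. A candidate explanation is active Wnt signalling: of 8 targets not looked at before, 7 were highest in tumor 4, Axin2 with 206 CPM against at most 15.8 elsewhere, with Lgr5 the exception. Wif1, Nkd1 and Lef1 of the same pathway had already been seen high in tumor 4, so a high count was likely beforehand. High Wnt targets also do not test why the neural stem and glial RNA was low. A wrong label, an outside sample and a property of line 90, which this tumor alone represents, stay open.

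The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many genes (206, the highest other 2) and the 1 split with as many lists (21, the highest other 20, with tumors 21 and 4 and control 7 on a side). By camera with the preset correlation the other splits called from 4 to 20 lists. Called lists by that test were thus not particular to tumors against controls. With an estimated correlation every split called 0 lists. DESeq2 called 1770 genes in the real split and from 4 to 159 in the others. The other splits put the difference between tumors and controls into the spread within groups, so few edgeR calls there were likely beforehand.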
